A study of Mus musculus with 3 samples.

How the data were processed

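Gene expression was measured in mouse embryos of embryonic day 8.75 on 3 Agilent arrays with 2 colours each. Per the labels, every array held wild-type RNA in the Cy3 (green) channel and Brpf1-deficient RNA in the Cy5 (red) channel, and the arrays are numbered as embryo pairs 1 to 3. No array carried the dyes the other way round, so dye and genotype cannot be separated. The labels do not say whether an RNA came from 1 embryo or from several. The p-values therefore measure the spread between these 3 pairs.

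Per the labels' protocols, 350 ng of total RNA went through 1 round of amplification, and the product was coupled to Cy dyes. Per the file headers, the scans were read with Feature Extraction 10.7.3.1, and all 3 arrays share 1 slide and 1 scan time, so neither could be tested as a batch. The intensity values used are the median brightness of each spot and of its local background on a linear scale, per the file headers. The files also hold processed signals that the scanner software had background-subtracted and dye-normalized, and log10 ratios of Cy5 over Cy3 made from them, per the file headers. A deposited table of the authors lists a log2 ratio, a mean log2 intensity, an unadjusted and an adjusted p-value and 2 scores (a moderated t and log odds) for 40000 probes. The submitters' processing notes name limma without a version, and the settings behind the table are not given in the sources used here. It holds the 40000 smallest p-values of 55821 probes, as the ratio of its largest adjusted p (0.749) to its largest p (0.537) shows, since the array also holds 55821 probes with controls. The authors' table does not state the direction of its ratio. Across 39908 shared probes it correlates at -0.802 with the mean log2 ratio of Cy5 over Cy3 computed here, so it runs as Cy3 over Cy5.

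The analysis started from the median signals, because the scanner files used here hold no mean signals, which had been planned. Background was corrected with normexp (offset 50), and log2 ratios of Cy5 over Cy3 were normalized within each array by loess (span 0.3) with control and outlier spots at weight 0. Outlier spots were then left out and spots of 1 probe were averaged. A probe was kept if it was well above background in the same channel on at least 2 of the 3 arrays, by at least 0.5 of its spots, which left 31598 of 55681 probes. One probe stood for each gene, the brightest by mean log2 intensity over both channels, which gave 23554 genes and other transcripts. Probes were named through their RefSeq accessions with the GRCm38.p6 gene table, used for names and gene order only. Of 29123 probes with such an accession, 27656 were matched to 1 gene, and 15377 of the genes tested carry such a name. The remaining 8177 include intergenic RNA intervals, named by their position on the mm9 build per the file headers. Of 36 named genes with several probes, 10 had probes on both sides of 0, and those singled out are named in the results.

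The mean log2 ratio over the 3 pairs was tested against 0 with limma 3.58.1 (lmFit and eBayes, intercept only, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all 23554 genes and a threshold of 0.05. Errors are moderated standard errors (SE) over 3 pairs. Where a gene was not well above background on any array in 1 channel, a floor was set for its intensity there. The floor was the lowest intensity of any probe well above background in that channel, after loess and Aquantile normalization. Where this floor changed the fold, the fold is given as a lower bound of the mean over the pairs. The bound makes no allowance for the spread between pairs and stays open to dye bias. In all, 27 gene lists were fixed before the data were examined. Of these, 26 were tested with camera (preset correlation 0.01, at least 5 measured members, Benjamini-Hochberg over the lists), and camera with an estimated correlation and fry were run beside it. The sex-linked list is given per pair. Genes were named by a rule fixed at the same time. It took the 12 largest increases and the 12 largest decreases among genes past the threshold with the same sign in all pairs, Brpf1 and its complex, and up to 4 members of each list by smallest unadjusted p. Names ending in Rik, starting with Gm and digits, LOC, ENSMUST, NAP or TC, and accessions were passed over. A gene outside that rule is said to have been chosen after its values were seen.

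Data were simulated with the moderated spread of each gene, as fitted by limma, and 200 changed genes among 23554. The test recovered 23.6% of genes changed by 0.5, 97.5% of those changed by 1 and 99% of those changed by 1.5 on the log2 scale, with a median of 16 false calls over 10 simulations. Moderation makes the spreads of all genes more alike than in the data and narrows those of the most variable genes. Recovery may therefore be overstated, most of all for the most variable genes. It also depends on the 200 changed genes put in. In the data Hoxd13, with a log2 ratio of -0.98 ± 0.21 (SE), did not pass over all genes. A shift of 0.3 in the 30 endothelial genes was called by camera in 100% of the simulations, which held no correlation between genes. Alternatives covered the background correction, the scanner software's processed signals, the normalization, the filter, the use of several probes, the variance model, a separate channel model, the omission of each pair, the thresholds, the authors' table and the set tests. A slide effect was not fitted because there is 1 slide. Narrower loess spans (0.1 and 0.02) and the omission of genes with a mean log2 intensity above 16.5, called the bright limit, were added after seeing the data. That limit was also chosen then.

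Median spot intensities were 149, 155.5 and 142.5 in Cy3 and 257, 257 and 234 in Cy5 for pairs 1, 2 and 3. Negative control spots had medians of 66, 61 and 62 in Cy3 and 116, 118 and 102.75 in Cy5. Between 54.2% and 59.9% of the probes were well above background in Cy3 and between 49.4% and 51.9% in Cy5. No spot was saturated. The number of arrays, 3, limits the precision of every value.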

Results

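RNA from mouse embryos at a stage of neural tube closure, heart looping and early blood circulation, was compared between wild-type and Brpf1-deficient embryos. Brpf1 encodes a scaffold protein that joins histone acetyltransferases of the KAT6 and KAT7 family to chromatin. Each of 3 arrays set 1 wild-type RNA (Cy3) against 1 Brpf1-deficient RNA (Cy5), as labelled, which gives 1 group of 3 pairs. Values are log2 ratios of Cy5 over Cy3, so a positive value stands for more signal in the channel labelled Brpf1-deficient. Across the 23554 genes tested, the log ratios of pairs 1 and 2 correlated at 0.409, those of pairs 1 and 3 at 0.335 and those of pairs 2 and 3 at 0.152. With a loess span of 0.02 the same correlations were 0.307, 0.173 and 0.0366. These correlations are across genes, which are not independent replicates.

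The first question was whether the disrupted gene itself was lower in the channel labelled Brpf1-deficient. It was higher. The log2 ratio of Brpf1 was 2.01, 1.43 and 1.06 in pairs 1, 2 and 3, with a mean of 1.499 ± 0.19 (SE, n = 3 pairs; limma adjusted p = 0.0405), a 2.83-fold difference. Its median spot intensity was 1772.5, 2125 and 1537 in Cy3 and 12356.5, 6418 and 5168 in Cy5. The authors' deposited table lists Brpf1 at -1.55 on the log2 scale (adjusted p = 0.289) and runs opposite to Cy5 over Cy3. The sign given here is therefore opposite to that of the authors' table, which does not state its direction. Turned to Cy5 over Cy3, the authors' value is 1.55, so Cy5 is the brighter channel in both. The labels do not say which part of the gene is disrupted, and where the only Brpf1 probe on the array lies relative to it was not analysed here. If the probe lies outside that part, it does not check the labels. All directions below are those of the channels as labelled, and none is assigned to a genotype. With a loess span of 0.02, chosen after seeing the data, the Brpf1 ratio was 1.52 ± 0.19 (SE), and the adjusted p was 0.273.

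None of the other 8 measured members of the BRPF1 acetyltransferase complex list passed the threshold over all genes. Meaf6, a subunit shared by these complexes, had a log2 ratio of -0.32 ± 0.08 (SE, adjusted p = 0.177), and Ing4, a histone reader, -0.30 ± 0.09 (adjusted p = 0.225). The paralogues Brd1 (0.17 ± 0.19) and Brpf3 (-0.20 ± 0.09) and the acetyltransferases Kat6a (-0.12 ± 0.08), Kat6b (0.10 ± 0.09) and Kat7 (-0.10 ± 0.09) lay near 0, as did Ing5 (-0.13 ± 0.09). Adjusted over the list alone, Brpf1 was higher and 1 member, Meaf6, was lower. As a set the list did not pass (camera, adjusted p = 0.68), with a median of -0.12 and a mean of 0.07.

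Past the threshold over all genes were 326 of the 23554 genes, 304 of them higher and 22 lower in Cy5, each with the same sign in all 3 pairs. By chance 25% of genes would have the same sign in all pairs, and 43.4% of all genes did. Since every array has the same dye orientation, dye bias of single probes would raise this share as a genotype effect would. At an unadjusted p below 0.05 there were 4086 genes, 1938 of them higher. The calls fell into 2 parts by brightness. Of the 304 higher genes, 280 were among the 544 genes with a mean log2 intensity above 17, and 43 calls, 21 higher and 22 lower, lay below the bright limit given with the processing. None of the 326 genes passed in limma after omission of any 1 pair (2125 to 3695 genes at an unadjusted p below 0.05), or with loess at a span of 0.02 (3508). With the genes above the bright limit left out, 0 of the rest passed (limma, smallest adjusted p = 0.291). The adjusted p-values of the dimmer calls below therefore depend on the bright genes being tested with them.

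Among the dimmer genes, 3 genes of heart muscle were lower in Cy5. Myh6, the atrial myosin heavy chain, had a log2 ratio of -0.70 ± 0.08 (SE, n = 3, adjusted p = 0.0313), Ryr2, the calcium release channel of cardiac muscle, -0.64 ± 0.09 (adjusted p = 0.0483) and Ttn, the sarcomere spring protein titin, -0.62 ± 0.08 (adjusted p = 0.0485). A second, dimmer Myh6 probe gave 0.11. These 3 were the only calls among 31 measured genes of the cardiomyocyte and heart field list, over all genes and adjusted over the list alone. Tnnt2, cardiac troponin T, had -0.36 ± 0.08 (adjusted p = 0.166). The list as a set did not pass (camera, adjusted p = 0.123), 10 members lay above 0, and the medians were -0.26, -0.33 and 0.04 in pairs 1, 2 and 3.

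Under the naming rule, which passes over Gm names among others, the largest decrease in Cy5 was that of Cyct, the testis form of cytochrome c. Cyct had a log2 ratio of -1.26 ± 0.16 (SE, adjusted p = 0.0414). Ces1d, a carboxylesterase, had -1.17 ± 0.15 (adjusted p = 0.039), 2.26-fold brighter in Cy3, and was not well above background in Cy5 on any array. Wdr93 had -1.07 ± 0.10 and Oprl1, the nociceptin receptor, -0.93 ± 0.11. Klk8, a serine protease (-0.77 ± 0.10), the zinc finger gene Zfp979 (-0.76 ± 0.08), Efcab1 (-0.73 ± 0.10) and Slc4a5, a bicarbonate transporter (-0.67 ± 0.08), were lower by smaller amounts. Zfr2 was not well above background in Cy5 on any array and had -0.69 ± 0.09, 1.62-fold brighter in Cy3 (adjusted p = 0.0462). Also lower were an intergenic RNA interval on chromosome 4 from 146890596 to 146891297 of the mm9 build (-0.82 ± 0.08, adjusted p = 0.0256) and another on chromosome 17 from 38132217 to 38157667 (-0.76 ± 0.09, adjusted p = 0.0346). Gm773, a larger decrease that the rule passed over, was chosen after its values were seen. It had -1.71 ± 0.17 and was at least 3.19-fold brighter in Cy3 in the mean of the pairs (adjusted p = 0.028).

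Below the bright limit 21 genes were higher, Brpf1 among them. Members of the fixed lists were Uncx, a homeobox gene of the posterior somite (0.75 ± 0.09, SE, adjusted p = 0.0376), Fabp7, a fatty acid binding protein of neural progenitors (0.60 ± 0.08, adjusted p = 0.0425), and Tex19.1, a germ cell gene kept silent by DNA methylation in most somatic tissue (1.07 ± 0.08, adjusted p = 0.0232). Chosen after their values were seen were Nrn1, which encodes neuritin (1.16 ± 0.14), Cer1, a secreted antagonist of Nodal and BMP (0.74 ± 0.09), Vax2, a homeobox gene of the ventral eye (0.64 ± 0.08), Aqp3, a water channel (0.71 ± 0.08), and Clec1b, a receptor of platelets and megakaryocytes (0.65 ± 0.09). The ratios of these 8 genes and of Myh6, Ryr2 and Ttn kept their sign and size with a loess span of 0.02, where Tex19.1 had 1.11 ± 0.08 and Myh6 -0.62 ± 0.08, but all adjusted p-values were 0.273.

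**Figure D1:**
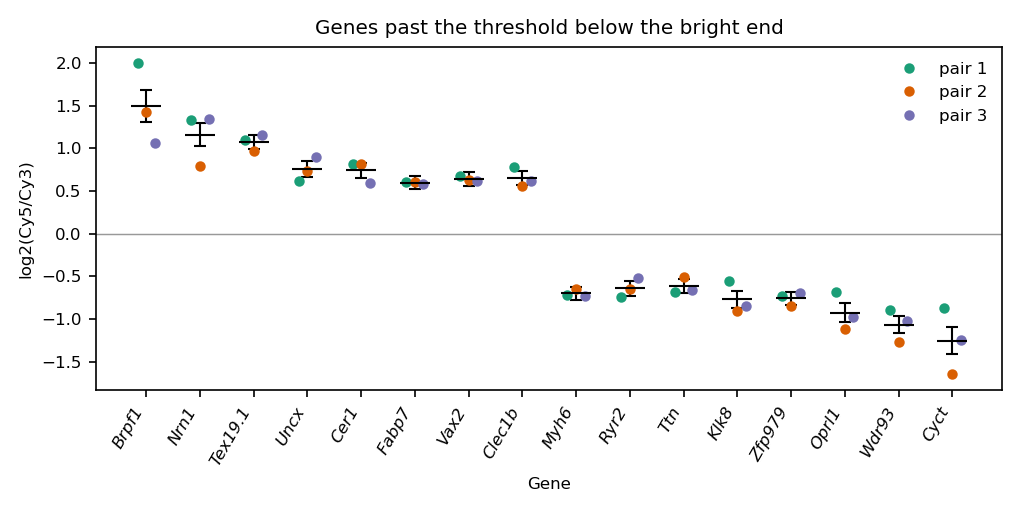
Log2 ratio of Cy5 over Cy3 (vertical axis) of 16 genes past the threshold below the bright limit, in pairs 1, 2 and 3 (coloured points); black lines are the mean and its moderated SE over 3 pairs. Brpf1 lies at 2.01, 1.43 and 1.06, and Myh6 at -0.72, -0.65 and -0.73.

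The other higher calls were bright probes. Of all 304 higher calls, 126 carry a matched gene name, as do 19 of the 22 lower ones. In the list ribosomal proteins the median log2 ratio was 0.85 (1.02, 0.74 and 0.85 in pairs 1, 2 and 3). Of 82 measured, 53 were higher and 29 did not pass, and adjusted over the list alone 75 were higher. Among the largest ratios were those of Rpl41 (2.83-fold), Rpl37a (log2 ratio 1.36 ± 0.11, SE), Rpl14 (1.35 ± 0.10) and Rps14 (1.29 ± 0.08), each with an adjusted p of 0.0232. Rps6 (1.26 ± 0.09) passed as well. Dimmer probes gave -0.22 for Rpl14 and 0.02 for Rps6, and another bright Rps6 probe gave 0.48. With the scanner software's processed signals, which put the median of all genes at -0.14, the list median was 0.0936 (camera adjusted p = 1.35e-13), Rpl41 had 0.84 and Rps6 -0.18. Camera gave an adjusted p of 5.6e-57 for the list, and an adjusted p of 0.9996 (unadjusted p = 0.0906) with an estimated correlation.

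Also among the largest ratios were those of 3 H2A histone genes, whose nearly identical transcripts were not told apart here, with H2ac11 at 1.43 ± 0.08 (SE), H2ac12 at 1.31 ± 0.08 and H2ac20 at 1.30 ± 0.08 (adjusted p = 0.0232 each). The same adjusted p belonged to Ppia, the abundant prolyl isomerase cyclophilin A (1.39 ± 0.09), Exosc2, an exosome subunit (1.37 ± 0.10), and an interval on chromosome 11 from 22681800 to 22707775 of mm9 (1.29 ± 0.10). The median ratio over all 544 genes above 17 was 0.88, 0.69 and 0.70 in pairs 1, 2 and 3, and over the 1075 genes between 15 and 16 it was -0.05, -0.10 and -0.06. With a loess span of 0.02, which centres the ratios at each intensity whatever their source, the median above 17 was 0.04, 0.01 and -0.01. The ratios became 0.38 ± 0.11 for Rpl41, 0.64 ± 0.08 for H2ac11 and 0.42 ± 0.09 for Ppia, and the ribosomal median was 0.10 (camera adjusted p = 6.19e-05, and 0.955 with an estimated correlation).

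**Figure D2:**
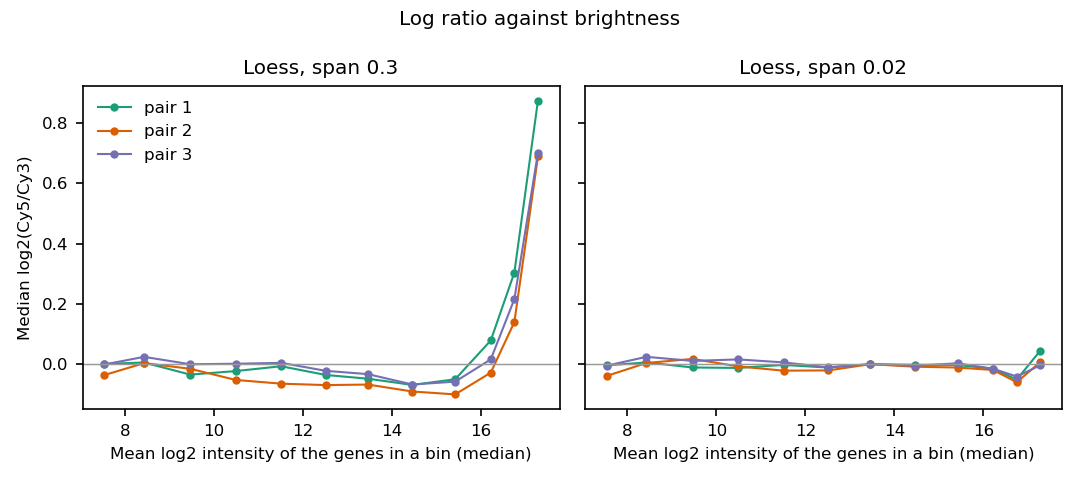
Median log2 ratio of Cy5 over Cy3 (vertical axis) of genes binned by mean log2 intensity (horizontal axis) in pairs 1, 2 and 3, with loess at a span of 0.3 (left) and 0.02 (right). Above an intensity of 17 the medians are 0.88, 0.69 and 0.70 on the left and 0.04, 0.01 and -0.01 on the right.

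The list visceral endoderm and yolk sac, of extraembryonic tissue that makes apolipoproteins and transport proteins at this stage, was higher in Cy5 as a set only in camera with the preset correlation. The median of 33 measured genes was 0.41, 31 of them were above 0, and camera gave an adjusted p of 1.25e-09 (0.9996 with an estimated correlation, unadjusted p = 0.119). Over all genes 1 member rose, Apoc2, a lipoprotein lipase cofactor (1.16 ± 0.12, SE, adjusted p = 0.0296), and 32 did not pass; adjusted over the list alone 9 were higher. The retinol carrier Rbp4 had 0.81 ± 0.11 (adjusted p = 0.0558), the glucose transporter Slc2a2 0.56 ± 0.09 (adjusted p = 0.0867) and Apoe 0.50 ± 0.08 (adjusted p = 0.087). The list median was 0.07, 0.46 and 0.54 in pairs 1, 2 and 3, and 0.35 with a loess span of 0.02. It was 0.22 with processed signals and between 0.26 (without pair 3) and 0.47 (without pair 1) when 1 pair was omitted. Apoc2, Rbp4 and Apoe lie above the bright limit and moved more with a span of 0.02. Apoc2 went to 0.79 ± 0.08 (limma adjusted p = 0.273), Rbp4 to 0.33 ± 0.13 and Apoe to 0.18 ± 0.09. With processed signals Apoe had 0.00881.

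The list extracellular matrix was lower as a set only with the preset correlation, with a median of -0.20 over 34 measured genes (camera, adjusted p = 0.00746, and 0.9996 with an estimated correlation, unadjusted p = 0.439). No member passed over all genes or adjusted over the list alone. Vcan, a proteoglycan of the cardiac jelly, had -0.49 ± 0.09 (SE, adjusted p = 0.102; other probes reached 0.34), Col6a1 -0.80 ± 0.18 (adjusted p = 0.15), Has2, a hyaluronan synthase, -0.51 ± 0.12 (adjusted p = 0.166) and Col9a1 -0.49 ± 0.13 (adjusted p = 0.194; its other probe 0.02). The medians were -0.29, -0.44 and 0.18 in pairs 1, 2 and 3, and those of the decidua and uterus list, which shares a few of its genes, had the same signs (-0.17, -0.49 and 0.41). Without pair 1 or pair 2 the set no longer passed (camera adjusted p = 0.148 and 0.211), nor did it with processed signals (0.0716) or median centring (0.0698). The median of the extracellular matrix list ranged from -0.37 to -0.06 when 1 pair was omitted.

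The hypoxia and glycolysis list held bright and dim genes that differed. Of 39 measured, 2 were higher over all genes, Ldha, lactate dehydrogenase (1.25 ± 0.10, SE, adjusted p = 0.0232), and Gapdh (0.92 ± 0.11, adjusted p = 0.0353), and 37 did not pass, while adjusted over the list alone 6 were higher and 12 lower. Other Ldha probes gave 0.68 and 0.30, and other Gapdh probes between 0.41 and 0.88. The glycolytic genes Eno1 (0.76 ± 0.11, adjusted p = 0.0622) and Pgk1 (0.45 ± 0.09, adjusted p = 0.139) lay among the bright genes as well. With a loess span of 0.02 Ldha had 0.52 ± 0.11, Eno1 -0.09, Gapdh -0.12 and Pgk1 -0.36. The list median moved from -0.07 to -0.27, and the camera adjusted p from 0.639 to 1.42e-05 (0.955 with an estimated correlation). In the immediate early and heat shock list, 2 of 25 were higher, the chaperones Hspa8 (0.70 ± 0.08, adjusted p = 0.0363) and Hsp90aa1 (0.64 ± 0.09, adjusted p = 0.0476), over all genes and over the list alone. They were at -0.13 and 0.07 with a span of 0.02, and Hsp90aa1 was at -0.07 with processed signals. The set had a camera adjusted p of 0.0934.

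Blood and vessel genes differed between the pairs. In the primitive erythroid list 1 of 27 genes was higher over all genes and over the list alone, the embryonic globin Hbb-bh1 (1.28 ± 0.16, SE, adjusted p = 0.0419; 0.23 ± 0.36 with a span of 0.02), and the embryonic alpha-like globin Hba-x had 0.55 ± 0.20 (adjusted p = 0.274; -0.34 with a span of 0.02). The list medians were -0.50, 0.36 and 0.11 in pairs 1, 2 and 3, and the camera adjusted p was 0.9996. No gene of the endothelial list (30 measured, median 0.09, camera adjusted p = 0.15) passed. Plvap, a protein of vessel fenestrae, had 0.49 ± 0.10 (adjusted p = 0.137) and the Notch ligand Dll4 0.32 ± 0.08 (adjusted p = 0.18). With a loess span of 0.02 the endothelial set had a median of 0.14 and a camera adjusted p of 0.0312, and 0.955 with an estimated correlation (unadjusted p = 0.407).

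Lists of the embryo's axis and germ layers did not pass as sets. Of 33 measured Hox genes, which set position along the body axis, none passed over all genes, while adjusted over the list alone 1 was higher and 4 lower (median -0.12, camera adjusted p = 0.193). Hoxb6 had 0.54 ± 0.10 (SE, adjusted p = 0.105), Hoxc4 -0.43 ± 0.08 (adjusted p = 0.118), Hoxb2 -0.39 ± 0.08 (adjusted p = 0.139) and Hoxd13 -0.98 ± 0.21 (adjusted p = 0.139). In the presomitic mesoderm and somite list (30 measured, camera adjusted p = 0.9996) Uncx was the only call, and adjusted over the list alone 1 was higher and 2 were lower. The segmentation gene Mesp2 had -0.50 ± 0.08 (adjusted p = 0.0893) and Greb1 -0.45 ± 0.08 (adjusted p = 0.102). In the neural plate and neural tube list (37 measured, 0.9996) Fabp7 was the only call, over all genes and over the list alone, and the Notch ligand Dll1 had -0.41 ± 0.10 (adjusted p = 0.166). No member passed in the lists of neural crest (25 measured, camera adjusted p = 0.639), gut and notochord (25, 0.9996) or limb and lateral plate mesoderm (23, 0.933), over all genes or over the list alone. Examples are Nkx2-3 (0.52 ± 0.09) of the gut and notochord list and Lix1 (-0.33 ± 0.17) of the limb list.

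Proliferation, stress and metabolic lists did not pass either. Among 25 measured p53 targets and CDK inhibitors (camera adjusted p = 0.9996) none passed over all genes, and 1 was higher over the list alone, Sesn2, a stress-induced regulator of mTORC1 (0.59 ± 0.10, SE, adjusted p = 0.0885). Cdkn2a, the senescence-associated inhibitor, had 0.57 ± 0.15 (adjusted p = 0.189). The related inhibitors Cdkn2b (-0.48 ± 0.12, adjusted p = 0.17) and Cdkn2c (-0.94 ± 0.27, adjusted p = 0.208) lay on the other side of 0. No member passed over all genes or over the list alone among 44 cell cycle and DNA replication genes (median -0.05, camera adjusted p = 0.639), 29 genes of the ATF4 and integrated stress response (-0.02, 0.9996), 25 of cholesterol synthesis (0.01, 0.9996) and 31 signalling pathway targets (-0.07, 0.67). Examples are Mki67 (-0.31 ± 0.10, adjusted p = 0.246), Ero1a (-0.39 ± 0.09, adjusted p = 0.149) and the Hedgehog target Gli1 (-0.55 ± 0.19, adjusted p = 0.251).

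In the germline gene list (21 measured, camera adjusted p = 0.772) Tex19.1 was the only call over all genes. Adjusted over the list alone 2 genes were higher and 3 lower, and the meiotic gene Sycp3 had -0.36 ± 0.08 (SE, adjusted p = 0.141) and Fkbp6 0.84 ± 0.20 (adjusted p = 0.167). In the pluripotency and primordial germ cell list (28 measured, 0.68) none passed over all genes, and 1 was lower over the list alone, Ifitm3 (-0.60 ± 0.09, adjusted p = 0.0587). None of 33 imprinted genes (0.9996) passed on either adjustment, and Magel2 had -0.50 ± 0.13 (adjusted p = 0.183).

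Markers of trophoblast, decidua and blood leukocytes, tissues and cells that can remain with a dissected embryo, passed neither singly nor as sets. The visceral endoderm and yolk sac list, also of extraembryonic tissue, did pass in camera with the preset correlation (adjusted p = 1.25e-09), as given above. Whether the amount of such tissue differed between the channels was not tested. The trophoblast and placenta list (18 measured, camera adjusted p = 0.849) had medians of -0.28, -0.32 and 0.41 in pairs 1, 2 and 3. The decidua and uterus list (23 measured, 0.31) had -0.17, -0.49 and 0.41, with the gap junction gene Gja1 at -0.31 ± 0.10 (SE, adjusted p = 0.235). The blood leukocyte list (17 measured, 0.36) had -0.44, -0.03 and -0.01. Of its members 4 lay above 0, among them Fcgr3 at 0.53 ± 0.15 (adjusted p = 0.204). The median and the test differed in sign for the lists of primitive erythroid, presomitic mesoderm, limb, cholesterol synthesis and imprinted genes. The mean differed in sign from the median for p53 targets, neural plate and the BRPF1 complex, as it did for the primitive erythroid, presomitic, cholesterol and imprinted lists.

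**Figure D3:**
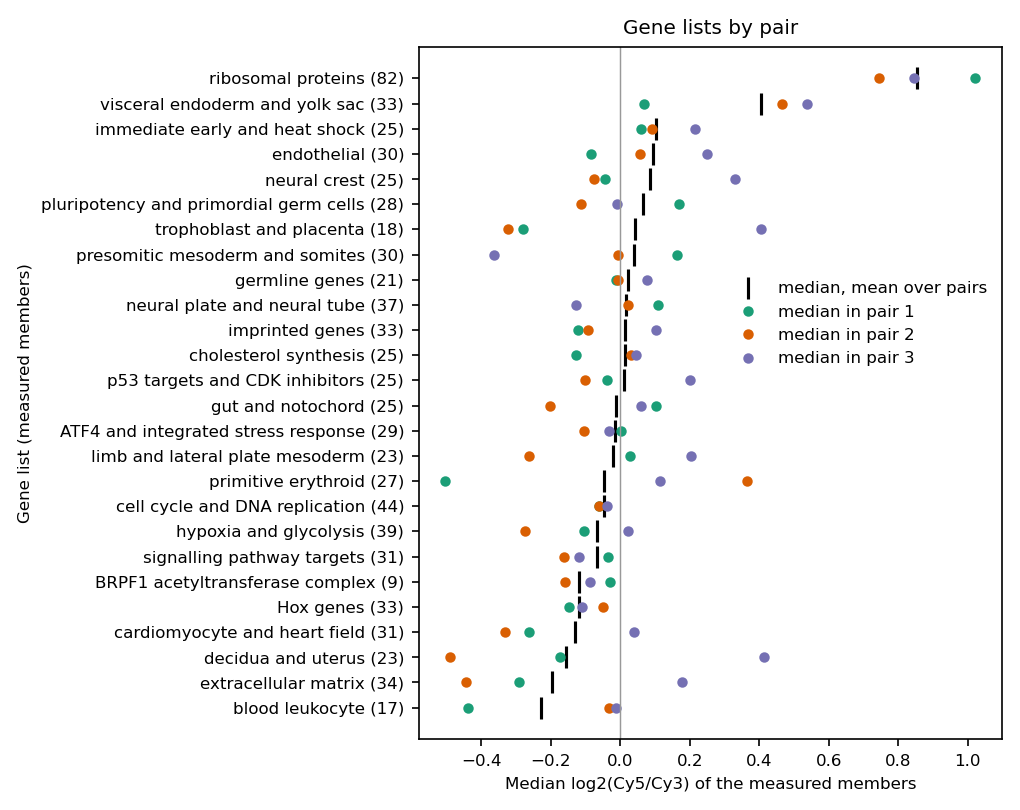
Median log2 ratio of Cy5 over Cy3 (horizontal axis) of the measured members of 26 gene lists in pairs 1, 2 and 3 (coloured points) and of the members' means over the pairs (black bars). The visceral endoderm list lies at 0.07, 0.46 and 0.54, and the trophoblast list at -0.28, -0.32 and 0.41.

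The sex-linked genes differed between pairs. Eif2s3y, a Y-linked translation factor gene, had fitted log2 ratios of 6.78, 0.02 and -5.49 in pairs 1, 2 and 3, and Ddx3y, a Y-linked RNA helicase gene, 5.92, -0.23 and -5.23. Xist, the RNA expressed from the inactive X chromosome, had -0.04, 0.29 and 2.69 with 1 probe and -0.15, -0.18 and 3.51 with another. Eif2s3y was not well above background in Cy3 of pair 1 (79) and Cy5 of pair 3 (154.5), so the sizes of its ratios there, like those of Ddx3y, depend on the background. In pair 1 Ddx3y was not well above background in Cy3 (77.5) and was at 8184 in Cy5, where Xist was at 2465, against 1517 in Cy3. In pair 2 Ddx3y was at 4890 and 4666 and Xist was not well above background in either channel. In pair 3 Ddx3y was at 4098 in Cy3 and not well above background in Cy5 (159), and Xist was at 149 in Cy3 and 1582 in Cy5. The other Xist probe was at 95 in that Cy3 channel, not well above background, while the first was. Of the remaining Y-linked genes, Uty reached an intensity of at most 469 and Kdm5d of at most 182.

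**Figure D4:**
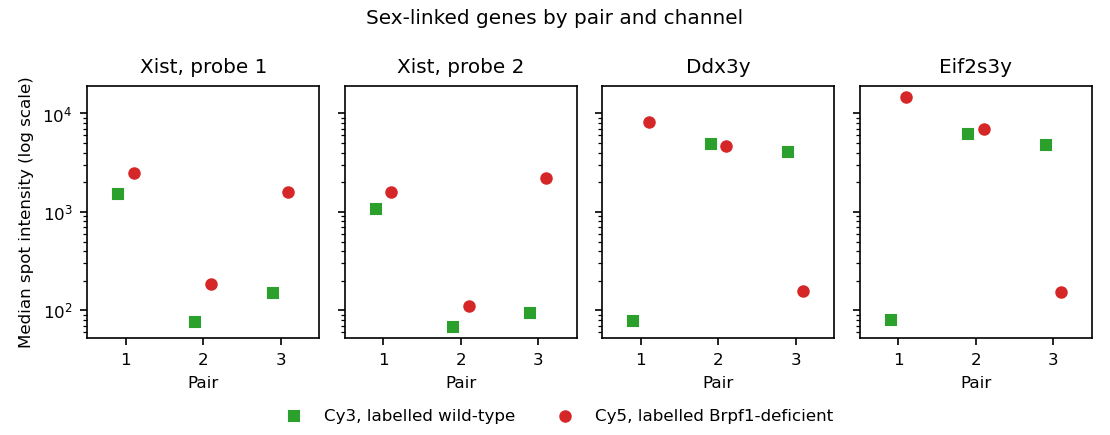
Median spot intensity on a log axis (vertical) of probes for Xist, Ddx3y and Eif2s3y in pairs 1, 2 and 3 (horizontal), in Cy3 (squares) and Cy5 (circles). In pair 1, Cy5 shows Xist at 2465 and Ddx3y at 8184, while Cy3 shows Xist at 1517 and Ddx3y at 77.5.

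In the authors' deposited table no probe passed an adjusted p of 0.05, the smallest adjusted p was 0.264, and 5725 probes had an unadjusted p below 0.05. The authors' deposited table lists Rps14 at -1.26 and Rpl41 at -1.47 on the log2 scale, and 21478 of its ratios are below 0 and 18522 above. Among 18105 shared probes well above background in both channels on all arrays, 99.5% had opposite signs in the authors' deposited table and in Cy5 over Cy3, as had 92.4% of all 39908 shared probes.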

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

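Narrower loess spans and the omission of bright genes were chosen after the results were seen. The Brpf1 ratio stayed above 0 under every alternative run, between 1.25 (without pair 1) and 1.72 (without pair 3) when 1 pair was omitted, but its adjusted p (limma, Benjamini-Hochberg) ranged from 0.00319 to 0.289. It missed the threshold without pair 1 (adjusted p = 0.194), 2 (0.1002) or 3 (0.101), and with a normexp offset of 10 (1.52), processed signals (1.44), scale normalization (1.52), the mean of all probes (1.499), the authors' table with its sign turned (1.55), and loess spans of 0.1 (1.52) and 0.02 (1.52, also with trend and robust variances). The number of genes past the threshold, 326, became 115 with offset 10, 651 with median centring (626 higher, 25 lower), 201 with the mean of all probes, 799 with the separate channel model (586 higher, 213 lower), 550 at an adjusted p of 0.1 (460 higher, 90 lower) and 121 with an absolute log2 ratio of at least 1. It was 0 with processed signals (4909 genes at an unadjusted p below 0.05), scale normalization (4327), the authors' table (3147), spans of 0.1 (3780) and 0.02 (3508, or 3520 with trend and robust variances), without the bright genes (3397) and, from 0 to 0, without any 1 pair (2125 to 3695). It lay between 321 and 423 with no background correction, Aquantile, no filter, a strict filter or trend and robust variances. The cause was not tested, except that omission of a pair leaves fewer samples and that the calls lost with a narrow span are weighed under the other observations. The 3 gene lists became 0 with an estimated correlation and 0 with fry, 5 with spans of 0.1 and of 0.02 (also with trend and robust variances), and 4 to 6 without 1 pair. Ratios on the other side of 0 were those of Hsp90aa1 (-0.0703) and Rps6 (-0.18) with processed signals, which move the median of all genes to -0.14, of Tgm4 (-0.12) without the filter, where another probe stands for the gene, and of Gapdh (-0.12) and Hspa8 (-0.13) with a span of 0.02 under both variance models. The cell cycle list passed as higher with median centring (median 0.0684), and the trophoblast list ranged from -0.21 to 0.16 without 1 pair. Over the other named genes and the alternatives with all pairs, 1869 comparisons kept direction and side of the threshold, 478 lost and 42 gained the threshold, and 24 changed sign without passing. Those that kept their side include genes that had not passed at first. Of the 61 other named genes past the threshold, 0 passed with processed signals, scale normalization, the authors' table or spans of 0.1 and 0.02. Without any 1 pair 0 passed as well. The slide as a block was not run, with 1 slide, and the authors' table and the separate channel model gave no set test. Cy5 background, with 49.4% to 51.9% of probes well above it, limits dim genes.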

Other observations

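Tests named here were chosen after the result was seen, except the exchange of channels for the gene count and the comparison of genes near Brpf1. The first pattern is the higher Brpf1 signal in the channel labelled Brpf1-deficient. A trend with brightness is argued against, since the median ratio of genes of like brightness (11 to 12) was -0.02. The Brpf1 ratio was 1.52 with a loess span of 0.02. An exchange of channels on a single array is argued against as the source, since the ratio was above 0 on all 3 arrays and the others would stay as labelled. Whether 1 array was exchanged at all is a separate question that the sign of Brpf1 does not settle. An exchange of the channel names on every array may account for the higher Brpf1 signal, but no array of known orientation decides it. The authors' deposited table lists Brpf1 at -1.55 and correlates at -0.802 with Cy5 over Cy3 across probes. A ratio taken as Cy3 over Cy5 gives both values with or without such an exchange, so they do not decide it either. Dye bias of the Brpf1 probe cannot be told apart from the genotype without a dye swap, although 0% of 2327 other genes of like brightness lay as far from 0. A biological explanation, such as a transcript kept or raised by a disrupted allele, was not tested.

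The second pattern is the set of 326 genes past the threshold. For the bright part as a whole an intensity-dependent dye difference and a real change shared by genes with bright probes cannot be told apart. Dimmer probes of Rpl14 (-0.22) and Rps6 (0.02) lacked the rise of the bright ones, which goes with the intensity-dependent difference. Those are few genes, and whether such probes measure the same transcripts was not checked. With a loess span of 0.02 limma called 0 genes (3508 at an unadjusted p below 0.05), but that span centres the bright genes under either explanation. For the 43 dimmer genes this trend is argued against as the source of the ratios, since their median absolute ratio was 1.01 times that before, and Myh6 went from -0.70 ± 0.08 to -0.62 ± 0.08. Their calls depended on the bright genes, and ended because the smallest adjusted p rose to 0.273 once the bright genes no longer had small p-values. With the genes above the bright limit left out, 0 passed in limma (smallest adjusted p = 0.291). Exchanging the channels of 1 array at a time gave at most 0 genes in limma (357 to 867 at an unadjusted p below 0.05) against the real 326 (1 of 4 sign patterns as large), too few patterns for a share below 0.05. Camera with the preset correlation called up to 13 gene lists against the real 3 (4 of 4 as large), so its list counts do not set the labelled order apart. With an estimated correlation the real 3 became 0. The exchanged patterns were not run that way, and the cause of their counts was not tested.

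The third pattern is the sign of the Y-linked genes, positive in pair 1 and negative in pair 3. An exchange of channels on 1 array stays open: the log ratios of pairs 1 and 3 correlated at 0.335 across genes and at 0.173 with a loess span of 0.02, and Brpf1 had the same sign in each pair, but dye bias of single probes, Brpf1 included, would keep both after an exchange. In pair 1 Ddx3y was at 77.5 in Cy3 and 8184 in Cy5, and in pair 3 at 4098 and 159. Within each of these pairs the RNAs therefore differed in Y-linked content whichever channel is which. An exchange could turn the sign of a pair but could not make this difference. Embryos of unmatched sex may account for the difference. Both Xist probes, Ddx3y and Eif2s3y were well above background in 1 channel, Cy5 of pair 1, which is consistent with RNA of both sexes there, and with 1 of the Xist probes (intensity 149) the same held in Cy3 of pair 3, so 2 channels in all. Whether RNAs were pooled is not stated in the labels, and a male and a female embryo in 1 tube, an admixture of tissue or a mix between samples were not separated.

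A further hypothesis was that a chromosome segment of another strain, carried along with the disrupted allele, changes genes near Brpf1. Of the 200 measured genes nearest to it (100 on each side, by gene order in GRCm38.p6), 15% had an unadjusted p below 0.05 with a loess span of 0.02, against 14.6% of all 15380 genes, a ratio of 1.03. That ratio lay above 50.3% of windows of the same size elsewhere, whose ratios had an SD of 0.173, and a segment that changes few genes may still be present.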
